A study of Homo sapiens with 9 samples.

How the data were processed

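RNA from DU145 cells treated with DMSO, H93 or SAHA was sequenced after 6 days, with 3 libraries per group. Per the labels' protocols, RNA was extracted with TRIzol, libraries were made with a stranded TruSeq mRNA kit, and the medium was changed daily. The authors deposited one table of FPKM per gene and library, a unit scaled for transcript length and library size. The submitters' processing notes name Trimmomatic 0.36, HISAT2, Cufflinks and the build GRCh38.p13, without roles, and the gene annotation and the use of strand are not given in the sources used here. Groups and replicate numbers came from the sample titles, and each table column was matched to 1 sample by its name. All value columns were used.

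The table held 16772 genes. Some 8 genes shared an Entrez identifier with another and were kept apart. Relative depths of 0.875 to 1.0 were read from the most common ratio of values under an FPKM of 0.1 between each library and the first. With these depths removed, 1738 genes with all values under 0.1 were checked for steps. In them 94.9% of the values were multiples of a step, within a tolerance of 0.02. A finer step was accepted for genes that failed on whole multiples of their lowest value. The absolute depth was unknown, reads were not recovered, and no counting interval was computed. Per library the FPKM summed to between 348656 and 355741, and the 10 highest genes held between 5.34% and 5.75% of it. No 2 libraries held the same nonzero value for a gene. Gene positions came from GENCODE release 29, matched by Entrez identifier, which covered 16623 genes and left 149 without a position.

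Values were analysed as log2(FPKM + 1), with genes kept at an FPKM of at least 1 in at least 3 of the 9 libraries, which left 11525. Differences are on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. limma 3.58.1 in R 4.3.3 was fitted to all 9 libraries with group means, a mean-variance trend and empirical Bayes moderation (6 residual and 6.05 prior degrees of freedom). All tests were two-sided, with Benjamini-Hochberg adjustment over the kept genes of a comparison. A 2-fold call needed an adjusted p under 0.05 and an absolute log2 difference of at least 1, and counts at adjusted p alone are given beside it. With 3 libraries against 3 an exact permutation test cannot go below p = 0.1, so single genes were not tested that way. Of 40 gene lists fixed from textbook knowledge, 35 had at least 5 kept members. They were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over those 35, and again with a correlation estimated for each list. That estimate was the same in every comparison and ran from -0.101 to 0.3653 over the lists. For some lists it lay below the preset, so a call lost with it need not mean correlated members. List members were also counted after adjustment over the list alone.

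Design, lists, alternatives and the rule for named genes were set before the data were examined. The rule took 8 genes tied to the compounds' targets, the 10 largest rises and 10 largest falls per comparison among called genes with non-overlapping groups, up to 4 members with the largest absolute difference of each list described, and genes of the near-zero classes. The shared DMSO libraries were handled by 100 simulations of unchanged groups. The procedure was tested on simulated data for H93 against DMSO with 200 of 11525 genes changed. Scored at adjusted p under 0.05 alone, it recovered 96.5% of those changed 1.5-fold, 98.7% of those changed 2-fold and 100% of those changed 4-fold. Of the genes passing 3.43% were false, and a comparison without changes gave 0. The 2-fold call itself was not scored, and the simulation changed fewer genes than the 8050 that passed in the data.

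Alternatives were pseudocounts of 0.1 and 5, no filter on low values, a mean FPKM of at least 5, median-ratio rescaling, quantile normalization, a fixed sum per library, robust moderation, a fit to the 6 libraries compared, the replicate number as a block, leaving out each library, an estimated correlation, and fry. Replicate numbers were not used to pair libraries, since same-numbered libraries did not deviate together. No batch or date is given in the labels, so no batch was modelled. The list of mitochondrially encoded mRNAs had 0 members in the table and was not analysed here. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.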

Results

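Gene expression was measured by RNA sequencing in DU145 cells, an established human prostate carcinoma line, after 6 days in culture with 1 of 3 treatments. The groups were the solvent control DMSO, the compound H93 at 20 µM, and SAHA (vorinostat, a histone deacetylase inhibitor) at 500 nM, with 3 libraries each. The labels write the doses as 20 μm and 500 nm, and they are read here as micromolar and nanomolar. The series title calls H93 a compound targeted at UHRF1, a protein that recruits the maintenance DNA methyltransferase DNMT1 to newly replicated DNA, and the design sets H93 against both SAHA and DMSO. The deposited table gave FPKM for 16772 genes in 9 libraries. Absolute read depth was unknown. The read steps visible in low values put the libraries within 0.875 and 1.0 of the deepest, and between 14910 and 15295 genes were above 0 in a library. Pearson correlations of log2 values across genes lay between 0.9976 and 0.9983 for replicates, between 0.9724 and 0.9733 for DMSO and H93, between 0.9821 and 0.9834 for DMSO and SAHA, and between 0.9951 and 0.9954 for H93 and SAHA. The labels do not say that replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical only. Below, values are mean FPKM ± SD with n = 3, genes rose or fell where the limma adjusted p was under 0.05, and a 2-fold call also needed a log2 difference of at least 1.

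The first comparison asked what H93 changed relative to solvent. SERPINB2, a plasminogen activator inhibitor, rose from 3.69 ± 0.0803 in DMSO to 126 ± 3.36 in H93 (n = 3 each). MMP1, an interstitial collagenase, rose from 8.40 ± 0.413 to 102 ± 1.92, and ANKRD1, a transcriptional cofactor gene, from 79.1 ± 0.532 to 516 ± 8.16. SUSD2, a membrane protein gene, fell from 16.8 ± 0.845 to 0.900 ± 0.0934, and CEBPD, a transcription factor of the inflammatory response, from 49.4 ± 0.660 to 11.3 ± 0.554. UHRF1 fell from 51.6 ± 1.02 to 34.2 ± 1.25, while CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 20.8 ± 1.33 to 80.6 ± 0.734.

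In limma with Benjamini-Hochberg adjustment over 11525 genes, 263 genes passed the 2-fold call, 169 higher and 94 lower in H93. At adjusted p alone 8050 genes passed, 4017 higher and 4033 lower. The 2 groups did not overlap in 73.2% of the genes, where chance gives 10%, and no 2-fold call had overlapping groups. The other largest rises were ESM1, the cytokine gene IL24 (1.37 ± 0.171 to 35.9 ± 0.792), the keratin-associated protein gene KRTAP2-3 (1.27 ± 0.0888 to 31.2 ± 1.39), SERPINB7, AADAC, GKN1 and HLA-DRA. The other largest falls were the acute-phase gene SAA1 (10.4 ± 1.39 to 1.13 ± 0.353), LCN2 (8.34 ± 1.16 to 1.18 ± 0.121), TNNC1, NAPSA, DHRS3, APOC1, NPW and IER5L. In the GRCh38 annotation of GENCODE release 29, SERPINB2 lies on chromosome 18 from 63871692 to 63903890, SUSD2 on chromosome 22 from 24181259 to 24189110, UHRF1 on chromosome 19 from 4903080 to 4962154 and CDKN1A on chromosome 6 from 36676460 to 36687339, all as protein-coding genes.

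Among the genes named for the compounds' targets, DNMT1 fell from 96.0 ± 1.68 to 81.0 ± 0.921 with H93 (log2 difference -0.24, SE 0.0231, adjusted p = 1.2e-06, limma with Benjamini-Hochberg). DNMT3A, a de novo methyltransferase, fell from 3.81 ± 0.196 to 2.47 ± 0.132, and the histone deacetylase HDAC1 rose from 61.7 ± 0.7998 to 82.0 ± 1.91. DNMT3B (adjusted p = 0.184), HDAC2 (adjusted p = 0.487) and HDAC3 (adjusted p = 0.0762) did not pass in limma with Benjamini-Hochberg. HDAC3 did pass without SAHA replicate 2 (adjusted p = 0.0262) and with only the 6 libraries compared (adjusted p = 0.0323), at 26.9 ± 1.25 in DMSO and 28.7 ± 0.176 in H93. For UHRF1 the log2 difference was -0.58 (SE 0.0323, adjusted p = 1.01e-08), and for CDKN1A it was 1.91 (SE 0.0377, adjusted p = 1.39e-12), both in limma with Benjamini-Hochberg.

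Camera called 2 lists as higher after H93, both lost with an estimated correlation. Of 19 tested immediate early and MAPK target genes 17 rose and 1 fell, the same numbers adjusted over the list alone, including the phosphatase DUSP5 (74.3 ± 1.15 to 181 ± 3.84), SPRY4 (3.42 ± 0.0908 to 9.27 ± 0.252) and JUN (26.0 ± 0.778 to 47.7 ± 1.38). Camera gave this list an adjusted p of 3.37e-06, and adjusted p = 0.101 with an estimated correlation. Of 26 lysosome and autophagy genes 19 rose and 5 fell (19 and 6 adjusted over the list alone), including the lysosomal cholesterol carrier NPC2 (68.8 ± 2.01 to 149 ± 3.53) and MAP1LC3B, an autophagosome component (55.0 ± 0.467 to 106 ± 1.85). Its adjusted p was 0.00835, and adjusted p = 0.173 with an estimated correlation.

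Camera called 7 lists as lower after H93, all lost with an estimated correlation. Of 39 DNA replication genes 24 fell and 1 rose, the same adjusted over the list alone, such as the helicase subunit MCM4 (108 ± 1.08 to 68.4 ± 0.368) and CDC45 (29.6 ± 0.502 to 18.4 ± 1.44); camera adjusted p = 9.57e-05, and adjusted p = 0.0903 with an estimated correlation. Of 34 G2/M genes 24 fell and 1 rose, the same adjusted over the list alone, such as CCNB1, the cyclin of mitotic entry (102 ± 0.747 to 75.1 ± 1.30); adjusted p = 0.000849, and adjusted p = 0.101 with an estimated correlation. Of 26 homologous recombination genes 18 fell and 0 rose, the same adjusted over the list alone, with BRCA2 from 4.91 ± 0.194 to 3.54 ± 0.131. For homologous recombination camera gave adjusted p = 0.00226, and adjusted p = 0.173 with an estimated correlation. Of 27 ribosome biogenesis and MYC target genes 19 fell and 3 rose, the same adjusted over the list alone, with nucleolin NCL from 261 ± 5.50 to 183 ± 1.86. For ribosome biogenesis it gave adjusted p = 0.00103, and adjusted p = 0.136 with an estimated correlation. Of 11 fatty acid synthesis genes 8 fell and 2 rose, the same adjusted over the list alone, with the desaturase SCD from 151 ± 1.78 to 75.5 ± 0.748 and the regulator SREBF1 from 13.7 ± 0.745 to 4.63 ± 0.262. For fatty acid synthesis it gave adjusted p = 0.00594, and adjusted p = 0.101 with an estimated correlation.

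Of 22 NRF2 and oxidative stress genes 15 fell and 3 rose, the same adjusted over the list alone, and the members did not all go 1 way. KEAP1, the adaptor that targets NRF2 for degradation, fell from 21.8 ± 0.587 to 9.52 ± 0.232, UGDH fell from 71.4 ± 1.67 to 40.7 ± 1.24, and the aldo-keto reductase AKR1C3 rose from 1.69 ± 0.239 to 9.44 ± 1.37. For the NRF2 list camera gave adjusted p = 0.000849, and adjusted p = 0.0903 with an estimated correlation. Of 24 integrated stress response genes 15 fell and 5 rose, the same adjusted over the list alone, with DDIT4, an inhibitor of mTOR signalling, from 68.1 ± 1.38 to 26.5 ± 0.688 and the amino acid transporter SLC7A5 from 105.5 ± 0.666 to 64.1 ± 1.78, while the transcription factor gene ATF3 rose (log2 difference 0.88). For the stress response list it gave adjusted p = 0.0343, and adjusted p = 0.136 with an estimated correlation. Cholesterol synthesis genes (15 of 23 fell and 5 rose; 15 and 6 adjusted over the list alone) and ribosomal protein genes (21 of 37 fell and 3 rose; 20 and 3 adjusted over the list alone) lay at the threshold, each with a camera adjusted p of 0.0502. The cholesterol list passed without DMSO replicate 2 (0.0453), H93 replicate 1 (0.0404) or SAHA replicate 1 (0.043). The ribosomal list passed without DMSO replicate 2 (0.0251), SAHA replicate 1 (0.0334), SAHA replicate 2 (0.04) or SAHA replicate 3 (0.0363). With a pseudocount of 0.1 both passed (0.0498 for cholesterol synthesis and 0.0488 for ribosomal proteins), which took the number of lists called from 9 to 11. None of the 9 lists called by camera out of 35 kept its call with an estimated correlation, where 10 lists had an unadjusted p under 0.05. The estimate lay below the preset 0.01 for DNA replication (0.0091), fatty acid synthesis (-0.0042), NRF2 (-0.0083) and stress response (-0.0179). A higher correlation therefore does not account for the loss of those calls. For the rest of the called lists it lay between 0.0233 and 0.0736.

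Several lists that camera did not call held members that changed in both directions. Of all 11525 kept genes 4017 rose and 4033 fell, so changes in both directions do not by themselves set these lists apart. Of 16 DNA methylation machinery genes 8 fell and 4 rose, the same adjusted over the list alone (camera adjusted p = 0.24), among them MBD3 (30.0 ± 0.696 to 21.5 ± 0.554) and MBD1 (15.9 ± 0.551 to 22.1 ± 0.669), which bind methylated DNA or belong to that family. Of 25 tumour suppressor genes known for promoter methylation 9 rose and 14 fell, the same adjusted over the list alone (adjusted p = 0.426). GADD45A, a growth arrest gene, rose from 18.8 ± 1.20 to 54.6 ± 2.93, and CDH1, the epithelial cadherin, fell from 13.3 ± 0.0427 to 4.34 ± 0.334. Of 17 interferon-stimulated genes 9 fell and 5 rose, the same adjusted over the list alone (adjusted p = 0.3), with IRF7 from 2.87 ± 0.420 to 0.721 ± 0.0232. Of 22 NF-kB targets and cytokines 12 rose and 9 fell, the same adjusted over the list alone (adjusted p = 0.522), with CXCL8 rising from 47.7 ± 0.379 to 142 ± 4.04 and the complement gene C3 falling from 5.76 ± 0.358 to 1.20 ± 0.0676. Of 19 cancer-testis genes that had values, 17 stayed under an FPKM of 1 in all libraries, BRDT rose from 7.77 ± 0.606 to 11.4 ± 0.776, and PRAME stood at 11.8 ± 0.541 and 11.9 ± 0.430.

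**Figure D1:**
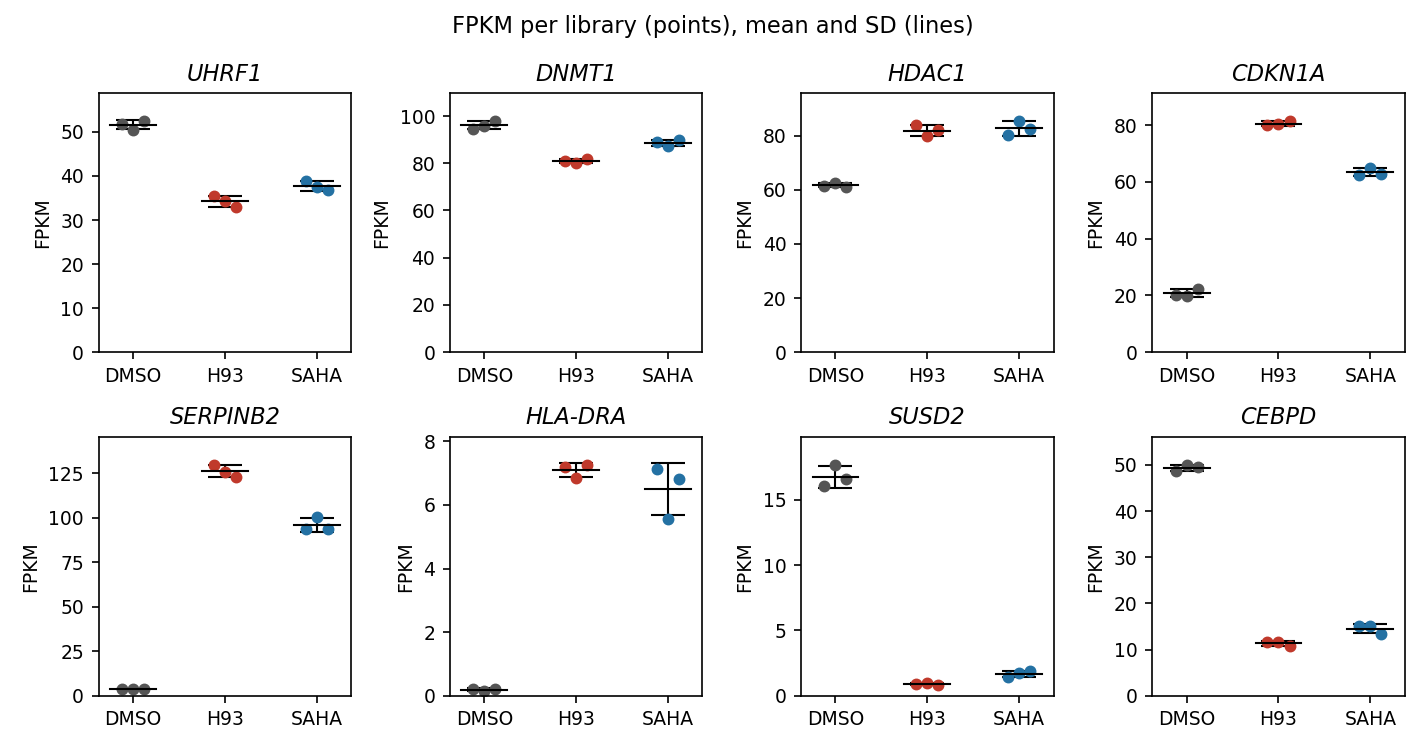
FPKM of 8 genes in each of the 9 libraries (points, by treatment), with the group mean and SD as black lines, on axes that start at 0. SERPINB2 stood at 3.69 in DMSO, 126 in H93 and 95.9 in SAHA, and UHRF1 at 51.6, 34.2 and 37.7.

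The second comparison asked what SAHA changed relative to solvent. SERPINB2 rose from 3.69 ± 0.0803 to 95.9 ± 4.09, IL24 from 1.37 ± 0.171 to 28.2 ± 1.65 and MMP1 from 8.40 ± 0.413 to 72.8 ± 3.07 (n = 3 each). SUSD2 fell from 16.8 ± 0.845 to 1.67 ± 0.255, SAA1 from 10.4 ± 1.39 to 1.11 ± 0.294 and CEBPD from 49.4 ± 0.660 to 14.5 ± 0.942. CDKN1A, a gene often raised by histone deacetylase inhibitors, rose from 20.8 ± 1.33 to 63.4 ± 1.35. UHRF1 fell from 51.6 ± 1.02 to 37.7 ± 1.08 and DNMT1 from 96.0 ± 1.68 to 88.7 ± 1.36.

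In limma with Benjamini-Hochberg adjustment 129 genes passed the 2-fold call, 86 higher and 43 lower in SAHA, and 6780 passed at adjusted p alone, 3159 higher and 3621 lower. Groups did not overlap in 64.1% of genes, where chance gives 10%, and 1 2-fold call had overlapping groups. Other named rises were ESM1, SERPINB7, AADAC, HLA-DRA, GKN1, KRTAP2-3 and the immune receptor gene SLAMF7 (1.24 ± 0.0380 to 7.38 ± 0.420), and other falls NPW, LCN2, IER5L, NAPSA, C3 and ARRDC3 (16.2 ± 0.416 to 5.07 ± 0.0889). BOLA2B, which has a near-identical copy, stood at 30.3 ± 38.2 and 4.55 ± 2.26 and is uncertain; its adjusted p of 0.0258 in limma with Benjamini-Hochberg became 0.1 without SAHA replicate 2, 0.123 with robust empirical Bayes and 0.0827 with no filter on low values. Its high DMSO mean came from DMSO replicate 1, at 74.4 against 9.08 and 7.34 in the other DMSO libraries. For UHRF1 the log2 difference was -0.44 (adjusted p = 2.22e-07), for DNMT1 -0.11 (adjusted p = 0.0011) and for HDAC1, at 82.7 ± 2.63, it was 0.42 (adjusted p = 1.12e-07), in limma with Benjamini-Hochberg. DNMT3A fell to 2.85 ± 0.165, whereas DNMT3B (adjusted p = 0.815), HDAC2 (adjusted p = 0.0611) and HDAC3 (adjusted p = 0.393) did not pass in limma with Benjamini-Hochberg. HDAC2 passed without SAHA replicate 1 (adjusted p = 0.0272) and with a fixed sum per library (adjusted p = 0.0484), and HDAC3 without SAHA replicate 2 (adjusted p = 0.0454).

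Of the immediate early and MAPK targets 14 rose and 1 fell after SAHA (15 and 1 adjusted over the list alone), with DUSP5 at 165 ± 0.341; camera adjusted p = 5.97e-06, and adjusted p = 0.0759 with an estimated correlation. Of 14 class I antigen presentation genes 9 rose and 4 fell, the same adjusted over the list alone, with HLA-B from 71.1 ± 2.04 to 130 ± 3.31 and B2M from 321 ± 5.82 to 476 ± 9.47, and the immunoproteasome subunit PSMB10 falling from 12.4 ± 1.119 to 7.77 ± 0.451. That list had adjusted p = 0.0419, and adjusted p = 0.166 with an estimated correlation; HLA genes share near-identical sequence and are uncertain one by one. Of 19 apoptosis regulators 10 rose and 2 fell (11 and 2 adjusted over the list alone), with the pro-apoptotic PMAIP1 rising from 13.9 ± 0.492 to 28.7 ± 1.51, the inhibitor BIRC2 rising from 26.1 ± 0.511 to 37.4 ± 1.34 and pro-apoptotic BID falling from 25.1 ± 0.402 to 14.4 ± 0.139. That list had adjusted p = 0.0419, and adjusted p = 0.166 with an estimated correlation. For H93 against DMSO 9 class I genes also rose and 4 fell, without a camera call (adjusted p = 0.123). Of the apoptosis regulators 12 rose and 3 fell with H93, also without a camera call (adjusted p = 0.103).

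DNA replication genes fell after SAHA in 20 of 39 cases and rose in 0, the same adjusted over the list alone, with MCM4 at 78.8 ± 1.04; camera adjusted p = 0.0014, and adjusted p = 0.0759 with an estimated correlation. Homologous recombination genes fell in 14 of 26 cases and rose in 0, the same adjusted over the list alone (adjusted p = 0.0178, and adjusted p = 0.283 with an estimated correlation), with BRCA2 at 3.70 ± 0.199. Of 23 cholesterol synthesis genes 12 fell and 4 rose, the same adjusted over the list alone, with INSIG1 from 11.1 ± 0.702 to 6.14 ± 0.307 (adjusted p = 0.0419, and adjusted p = 0.166 with an estimated correlation). Fatty acid synthesis genes fell in 8 of 11 cases and rose in 2, the same adjusted over the list alone, with SCD at 86.1 ± 1.59 (adjusted p = 0.00365, and adjusted p = 0.0759 with an estimated correlation). Integrated stress response genes fell in 16 of 24 cases and rose in 3, the same adjusted over the list alone, with DDIT4 at 32.9 ± 0.774 (adjusted p = 0.00171, and adjusted p = 0.0759 with an estimated correlation). NRF2 and oxidative stress genes fell in 17 of 22 cases and rose in 3, the same adjusted over the list alone, with KEAP1 at 11.8 ± 0.617 and AKR1C3 rising to 6.30 ± 0.474 (adjusted p = 9.66e-05, and adjusted p = 0.0759 with an estimated correlation). Ribosome biogenesis genes fell in 14 of 27 cases and rose in 2, the same adjusted over the list alone (adjusted p = 0.0169, and adjusted p = 0.244 with an estimated correlation), with UTP20 from 20.6 ± 0.590 to 14.6 ± 0.402. Of 10 replication-dependent histone genes 7 fell and 0 rose, the same adjusted over the list alone, with H2BC21 from 6.40 ± 0.0623 to 3.38 ± 0.0829 (adjusted p = 0.0142, and adjusted p = 0.252 with an estimated correlation). These transcripts normally lack poly(A) tails, and the libraries came from a poly(A) mRNA kit.

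Of the 11 lists called for SAHA, 3 lost the call without DMSO replicate 3: class I antigen presentation (adjusted p = 0.0504), apoptosis regulators (0.053) and cholesterol synthesis (0.053). Without SAHA replicate 2 apoptosis regulators (0.0583) and cholesterol synthesis (0.0528) lost it, and under median-ratio rescaling all 3 did (0.0558, 0.0521 and 0.0521). No list kept its call with an estimated correlation in camera, where 8 lists had an unadjusted p under 0.05. Of 7 genes known to respond to histone deacetylase inhibitors 2 rose, CDKN1A and GSN (13.2 ± 0.457 to 19.8 ± 0.849), and 4 fell, against 3 and 4 adjusted over the list alone. The list was not called (adjusted p = 0.904), and its median and mean differed in sign. DHRS2, a gene often raised by such inhibitors, stood at 0.0838 ± 0.00523 in DMSO and 0.0670 ± 0.0418 in SAHA.

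The third comparison set H93 against SAHA, at doses that differ (20 µM and 500 nM). KRTAP2-3 stood at 31.2 ± 1.39 in H93 and 11.1 ± 0.188 in SAHA. UHRF1 was lower in H93 (34.2 ± 1.25) than in SAHA (37.7 ± 1.08), DNMT1 was lower (81.0 ± 0.921 and 88.7 ± 1.36), and CDKN1A was higher (80.6 ± 0.734 and 63.4 ± 1.35; n = 3 each). Of 10 replication-dependent histones 9 were higher in H93, a list call that was lost with an estimated correlation (adjusted p = 0.0674), and H1-2 stood at 117 ± 3.27 and 84.8 ± 3.73. The mitotic kinase gene AURKB was lower in H93, at 61.4 ± 0.265 and 74.8 ± 0.836.

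In limma with Benjamini-Hochberg adjustment 2 genes passed the 2-fold call and 3629 passed at adjusted p alone, 2031 higher and 1598 lower in H93. This balance depended on the scaling, with 1751 of 3557 genes higher under median-ratio rescaling, 1693 of 3484 under quantile normalization and 2352 of 3747 with a fixed sum per library. Groups did not overlap in 44.4% of genes, where chance gives 10%. KRTAP2-3 was the higher gene (log2 difference 1.42, SE 0.0436, adjusted p = 2.38e-09, limma with Benjamini-Hochberg). The other was SMIM11A, named after its values were seen, at 0.954 ± 0.365 in H93 and 6.96 ± 5.90 in SAHA with overlapping groups (adjusted p = 0.0355, limma with Benjamini-Hochberg); it has a near-identical copy and is uncertain. The count of 2 became 1 without H93 replicate 2 and also without H93 replicate 3.

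For UHRF1 the difference between H93 and SAHA was -0.14 on the log2 scale (95% interval -0.21 to -0.07, adjusted p = 0.00795, limma with Benjamini-Hochberg). HDAC1 did not pass (log2 difference -0.01, interval -0.07 to 0.05, adjusted p = 0.749), nor did HDAC2 (interval -0.02 to 0.13, adjusted p = 0.267), HDAC3 (interval -0.05 to 0.15, adjusted p = 0.439), DNMT3B (interval -0.25 to 0.02, adjusted p = 0.179) or DNMT3A (interval -0.27 to -0.03, adjusted p = 0.0581), in limma with Benjamini-Hochberg. Without SAHA replicate 3 DNMT3B (adjusted p = 0.0343) and DNMT3A (adjusted p = 0.0452) passed. DNMT3A also passed under median-ratio rescaling (adjusted p = 0.0462) and quantile normalization (adjusted p = 0.0344).

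Camera called 12 of 35 lists between the compounds, 3 of them also with an estimated correlation. Those were G2/M genes, of which 20 of 34 were lower in H93 and 0 higher (22 and 1 adjusted over the list alone; adjusted p = 1.82e-09, and adjusted p = 0.0191 with an estimated correlation), DNA replication genes, with 20 of 39 lower and 1 higher (20 and 2 adjusted over the list alone; adjusted p = 1.08e-06, and adjusted p = 0.0191 with an estimated correlation), and hypoxia and glycolysis genes, with 14 of 26 lower and 1 higher (15 and 1 adjusted over the list alone; adjusted p = 1.98e-06, and adjusted p = 0.0191 with an estimated correlation). Thymidylate synthase TYMS stood at 130 ± 3.02 in H93 and 155 ± 1.27 in SAHA, and the glycolytic enzyme ENO1 at 692 ± 19.3 and 819 ± 16.6.

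The other 9 list calls were lost with an estimated correlation. Of the histones 9 of 10 were higher in H93 and 0 lower, the same adjusted over the list alone (adjusted p = 8.09e-06, and adjusted p = 0.0674 with an estimated correlation). Of the immediate early genes 13 of 19 were higher and 1 lower (14 and 1 adjusted over the list alone; adjusted p = 7.25e-06, and adjusted p = 0.0674 with an estimated correlation), with EGR1 at 9.39 ± 0.614 and 7.17 ± 0.190. Of the lysosome genes 13 of 26 were higher and 1 lower (14 and 1 adjusted over the list alone; adjusted p = 4.05e-05, and adjusted p = 0.0674 with an estimated correlation), with the proton pump subunit ATP6V1A at 25.0 ± 0.239 and 18.8 ± 0.271. Of 17 TGF-beta targets 7 were higher and 0 lower (8 and 0 adjusted over the list alone; adjusted p = 0.0136, and adjusted p = 0.251 with an estimated correlation), with CCN2 at 123 ± 2.02 and 82.3 ± 2.44. Of 14 cell cycle inhibitors 6 were higher and 0 lower, the same adjusted over the list alone (adjusted p = 0.0337, and adjusted p = 0.301 with an estimated correlation). That call ended without H93 replicate 1 (adjusted p = 0.0521), H93 replicate 3 (0.0608), SAHA replicate 1 (0.055) or SAHA replicate 3 (0.0549).

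Of 37 ribosomal protein genes 24 were lower in H93 and 0 higher (27 and 0 adjusted over the list alone; adjusted p = 8.99e-10, and adjusted p = 0.266 with an estimated correlation), with RPS3 at 365 ± 5.82 and 412 ± 15.7. Under quantile normalization the list median shrank from -0.0999 to -0.0397, and RPL4 (adjusted p = 0.0703), RPS2 (0.106) and RPL23 (0.061) no longer passed. These genes have many processed copies in the genome. Of 27 ribosome biogenesis genes 12 were lower and 0 higher (13 and 0 adjusted over the list alone; adjusted p = 4.86e-05, and adjusted p = 0.0674 with an estimated correlation), with NCL at 183 ± 1.86 and 220 ± 4.98. Of 26 homologous recombination genes 4 were lower and 0 higher, the same adjusted over the list alone (adjusted p = 0.00453, and adjusted p = 0.251 with an estimated correlation). Of 11 fatty acid synthesis genes 8 were lower and 1 higher (8 and 2 adjusted over the list alone; adjusted p = 0.00491, and adjusted p = 0.0674 with an estimated correlation), with FADS2 at 48.5 ± 2.11 and 57.3 ± 1.31.

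**Figure D2:**
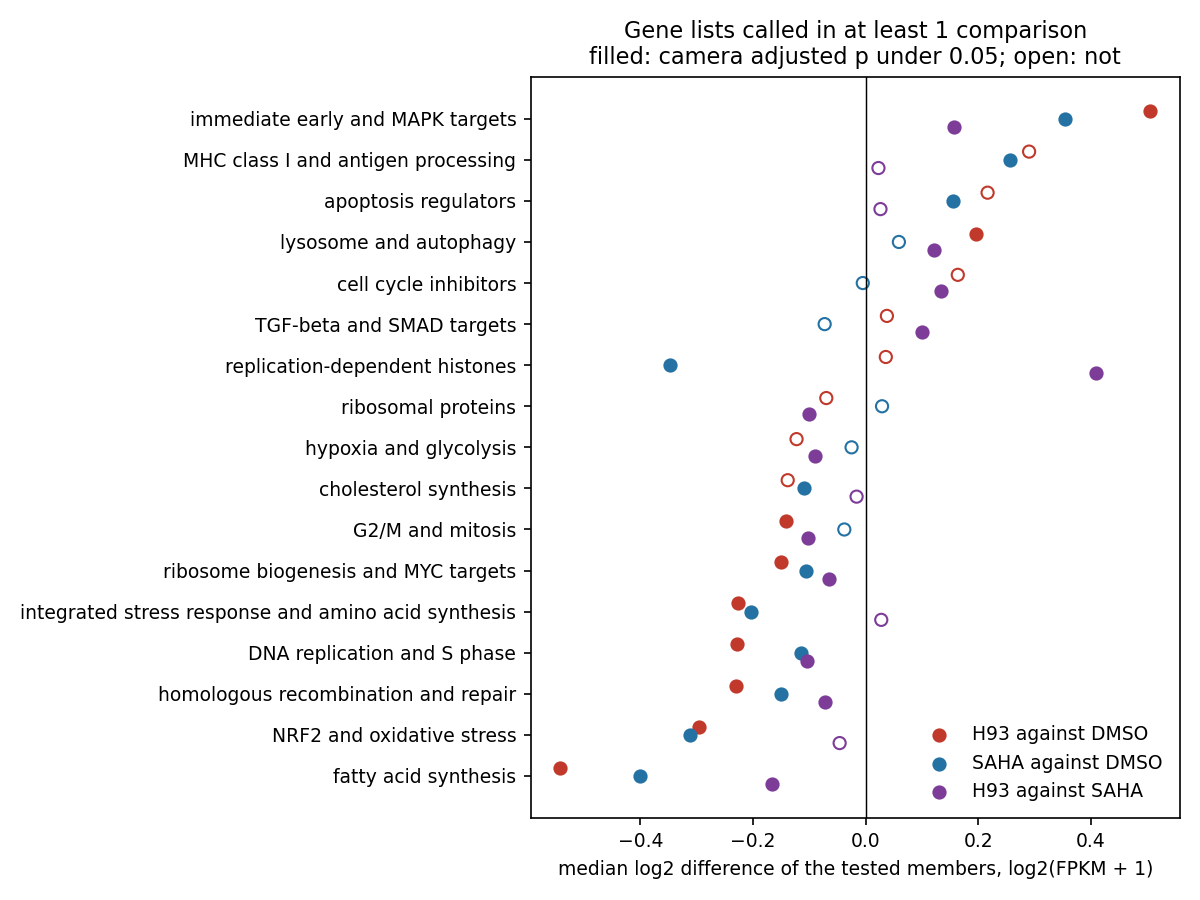
Median log2(FPKM + 1) difference of the tested members of each gene list called in at least 1 comparison, with 1 colour per comparison, filled where the camera adjusted p was under 0.05 and open where not. Histones lay at 0.04 for H93 against DMSO, -0.35 for SAHA against DMSO and 0.41 for H93 against SAHA; for SAHA against DMSO the ribosomal protein median changed sign under quantile normalization (-0.01) and that of cell cycle inhibitors under median-ratio rescaling (0.0043).

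The differences from DMSO were also compared between the compounds. Of the 2-fold calls 83 genes were higher in both and 41 lower in both, where independent lists would share 1.26 and 0.351, and 0 went in opposite directions. At adjusted p alone 2925 genes were higher in both and 3212 lower in both, where independent lists would share 1101 and 1267, and 25 differed in direction. Across the 11525 genes, which are not independent replicates, Pearson's r of the log2 differences was 0.948 and Spearman's rho 0.925, and 87.8% had the same sign. In 100 simulations 3 unchanged groups were drawn from the fitted spread, with 1 of them as the shared control. There r averaged 0.501 (highest 0.564) and 66.7% had the same sign, which follows from sharing 1 control and is no property of these DMSO libraries. The covariance was 0.113 against a simulated mean of 0.00157 (highest 0.00201), a difference of 0.111. The 3 DMSO libraries were too few to give each compound 2 separate controls, so part of the excess overlap may come from the shared controls. Of 2625 genes that passed both for SAHA against DMSO and for H93 against SAHA, 2286 (87.1%) lay further from DMSO in H93, at doses that were not matched.

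**Figure D3:**
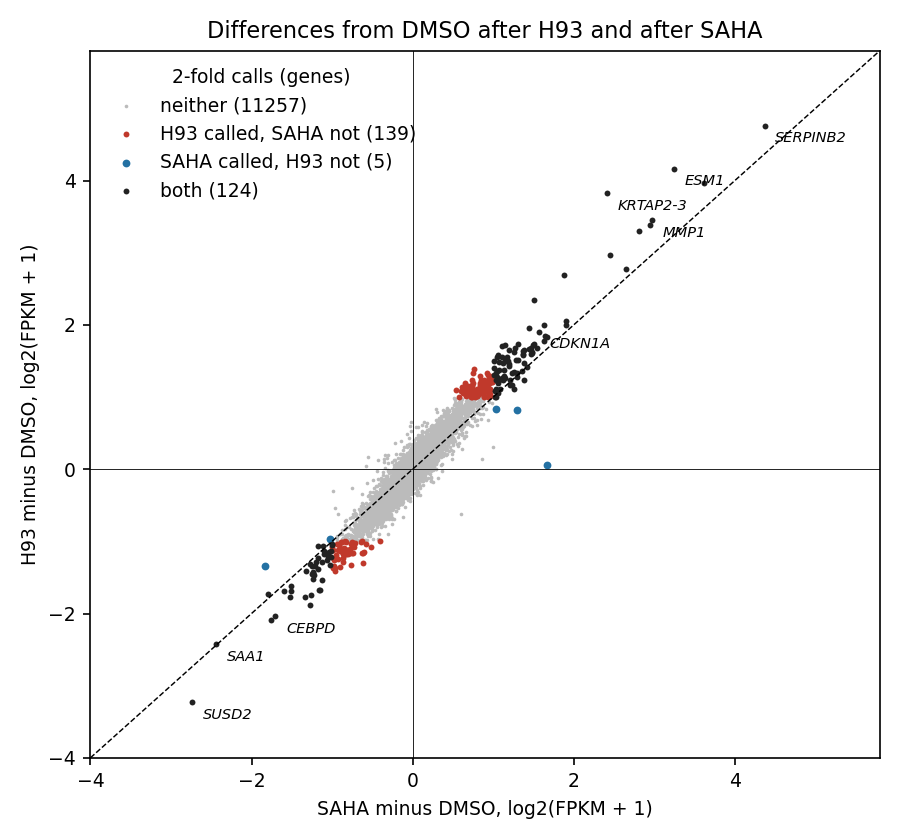
Log2(FPKM + 1) difference from DMSO after SAHA (x axis) and after H93 (y axis) for each of 11525 tested genes, coloured by 2-fold call, with a dashed line of equality. Both compounds had 124 genes called together, H93 had 139 more and SAHA 5 more, and r was 0.948.

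Few genes went from near zero to expressed. With FPKM under 0.1 in all 3 DMSO libraries and at least 1 in all 3 treated libraries, H93 had 1 gene, NTS, the neurotensin precursor (0.0279 ± 0.0242 to 1.70 ± 0.159), and SAHA had 0, with NTS at 0.746 ± 0.102. The reverse class held 1 gene for H93, the keratin gene KRT4 (1.24 ± 0.0547 to 0.0175 ± 0.0151), and 0 for SAHA. KRT4 also fell in SAHA, to 0.097 ± 0.0175 (adjusted p = 2.89e-08, limma with Benjamini-Hochberg). Its difference between H93 and SAHA did not pass in the same test (adjusted p = 0.189). The count of 1 for H93 became 4 without DMSO replicate 1 and 2 without DMSO replicate 2. These counts describe the libraries and carry no test.

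Markers of other cell types stayed low with exceptions. Of 11 leukocyte genes that had values, 6 were under an FPKM of 1 in all libraries, as were 10 of 12 fibroblast and endothelial genes and 5 of 9 luminal prostate genes. Mean FPKM of the fibroblast gene COL1A1 was 2.24 in DMSO, 3.2 in H93 and 3.245 in SAHA. For COL1A2 it was 0.371 in DMSO, 0.429 in H93 and 1.03 in SAHA. Among the leukocyte genes HLA-DRA rose from 0.187 ± 0.0404 to 7.10 ± 0.221 in H93 and 6.50 ± 0.826 in SAHA, CORO1A from 4.02 ± 0.237 to 13.99 ± 0.240 and 9.48 ± 0.735, and CD68 from 22.4 ± 0.341 to 28.3 ± 0.848 and 33.4 ± 1.75. CD74, the class II invariant chain, stood at 1.08 ± 0.174 in DMSO and 1.29 ± 0.165 in H93, which did not pass (adjusted p = 0.14 in limma with Benjamini-Hochberg), and rose to 1.92 ± 0.208 in SAHA.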

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

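Of the tests reported in this part, the S phase test was chosen after the result was seen, and the tests of length and GC content and of RNAs without poly(A) tails were written before their results were seen.

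Fixed lists stood out because their medians lay on opposite sides of DMSO in the 2 treatments and the direct test between H93 and SAHA passed at the preset correlation. With an estimated correlation none of the 4 passed: adjusted p = 0.301 for cell cycle inhibitors, 0.266 for ribosomal proteins, 0.251 for TGF-beta targets and 0.0674 for histones. Cell cycle inhibitors differed by a median log2 of 0.134 between H93 and SAHA. Against DMSO the medians were 0.16 and -0.01, the latter turning to 0.0043 under median-ratio rescaling. Their mean for SAHA against DMSO was 0.1822, with 5 members higher and 5 lower, so their opposite sides rest on the median alone. The camera call between H93 and SAHA ended without H93 replicate 1 (adjusted p = 0.0521) or H93 replicate 3 (0.0608). It also ended without SAHA replicate 1 (0.055) or SAHA replicate 3 (0.0549). Ribosomal proteins differed by -0.0999, which shrank to -0.0397 under quantile normalization (-0.07 and 0.03 against DMSO, the latter turning to -0.01), and TGF-beta targets by 0.1009 (0.04 and -0.07).

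Replication-dependent histones differed most, with a median of 0.4087 between H93 and SAHA (0.04 and -0.35 against DMSO) and 9 of 10 members higher in H93. Fewer cells in S phase after SAHA than after H93 would lower DNA replication genes in SAHA, but their median was lower in H93, at -0.1035. However, 87.1% of the genes that passed for SAHA against DMSO and between the compounds lay further from DMSO in H93. The list therefore cannot separate the share of cells in S phase from the size of the response, and cell phases were not measured. Against DMSO the median of the DNA replication genes was -0.2281 in H93 and -0.1149 in SAHA. Fewer cells in S phase after SAHA than after DMSO were therefore not excluded. A trend with transcript length and GC content was removed per library, and the histone median was then 0.4126 (adjusted p = 1.42e-06 in camera, and adjusted p = 0.0475 with an estimated correlation). A different yield of RNAs without poly(A) tails stays open, since 0 genes for small RNAs without tails were tested, and it cannot be told apart from a response to the compounds. A change in histone transcript processing or abundance that differs between H93 and SAHA may be biological, as a hypothesis found and tested on these libraries.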

How the results depend on the processing

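All alternatives here were planned before the data were examined. No named gene or list that passed at adjusted p under 0.05 changed direction. Small medians of uncalled lists did change sign with the scaling, such as p53 targets between H93 and SAHA (0.01, and -0.01 under quantile normalization). Each named gene in a comparison was counted once per alternative, at adjusted p under 0.05 alone and not by the 2-fold call. On that count 8900 results kept direction and side of the threshold, 111 no longer passed, 28 came to pass and 24 that did not pass changed sign. Lists were set only against a pseudocount of 0.1, median-ratio rescaling, the replicate block and leaving out each library. For lists these numbers were 1214, 12, 9 and 25.

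The number of 2-fold calls depended on settings that act on low genes. For H93 against DMSO, SAHA against DMSO and H93 against SAHA it was 540, 292 and 8 at a pseudocount of 0.1, 74, 30 and 1 at a pseudocount of 5, and 156, 78 and 1 at a mean FPKM of at least 5; a larger pseudocount shrinks differences of low genes and a stricter filter tests fewer genes. With adjusted p alone it was 8050, 6780 and 3629. For H93 against SAHA it was 1 with no filter on low values, 1 with robust empirical Bayes and 1 with only the 6 libraries compared, and the cause was not tested. Leaving out 1 library gave 261 to 274, 126 to 139 and 1 to 3 genes, 9 to 11, 8 to 11 and 11 to 12 lists, and r from 0.9408 to 0.9481 for the compounds. The lists called were 0, 0 and 3 with an estimated correlation in camera, where 10, 8 and 8 had an unadjusted p under 0.05, 32, 30 and 19 with directional fry, and 35 in each with mixed fry, which ask whether members move and not whether they differ from other genes. With the replicate block the counts were 264, 129 and 2 genes and 9, 11 and 12 lists, and r was 0.9478; same-numbered libraries correlated between -0.098 and 0.036 in their deviations, so the numbers did not pair them. Genes near zero in DMSO and expressed after H93 numbered 6 under limits of 0.1 and 0.5, 2 under limits of 0.3 and 3, and 1 to 4 when leaving out 1 library; the reverse class was 0 under limits of 0.3 and 3. For SAHA the first class was 3 and 1 under those limits, and 0 to 0 without 1 library. The cause of these changes was not tested. Absolute depth was unknown, so it sets no limit that can be stated here.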

Other observations

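Of the tests reported in this part, those of the shared DMSO libraries, of leukocyte RNA, of reads moved between class II genes and of CIITA were chosen after the result was seen, as were the class II list and the pathway test; the counts of other splits and the neighbour test were written before.

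Several HLA class II genes rose with both compounds. HLA-DQB1 rose from 2.23 ± 0.439 in DMSO to 9.23 ± 0.221 in H93 and 7.74 ± 0.246 in SAHA, HLA-DMA from 6.58 ± 0.401 to 16.1 ± 1.28 and 16.4 ± 0.606, and HLA-DRB1 from 5.21 ± 0.116 to 14.7 ± 1.02 and 14.2 ± 0.234 (n = 3 each). KEGG pathways taken from the file's own annotation were tested with camera, and 23, 23 and 16 of 306 were called for H93 against DMSO, SAHA against DMSO and H93 against SAHA. Allograft rejection, which holds HLA genes, had adjusted p = 1.02e-05 for H93 and 2.69e-08 for SAHA against DMSO. With an estimated correlation 0 were called in each, where 45, 51 and 29 had an unadjusted p under 0.05.

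For the class II genes, leukocyte RNA in the treated cultures would bring the abundant leukocyte genes along. The median FPKM gain of the 10 other list members was 0.139 in H93, beside 6.92 for HLA-DRA, although CORO1A and CD68, which DMSO cells also express, gained 9.97 and 5.96. Reads moved between near-identical class II genes would leave their sum unchanged, but it was 3.11 times that in DMSO (3.03 in SAHA). A rise of the transactivator CIITA stays open, since its mean in H93 was 0.02, too low to test. These genes may then rise through the compounds, with the route untested, and this remains a hypothesis found and tested on the same libraries.

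H93 and SAHA differed from DMSO in the same direction in most genes. Simulated noise of the shared DMSO libraries gave a covariance of up to 0.00201, against 0.113 observed. That simulation used the spread between libraries within groups, so it cannot cover an offset common to all DMSO libraries. At adjusted p alone 6137 genes passed in the same direction in both, and whether the compounds act through a common route was not tested. The 6 libraries of a comparison have 10 splits, the real one included, too few for a share under 0.05; 1 of 10 gave as many 2-fold calls in each comparison, the real split with 263, 129 and 2 genes, and the highest of the others had 0, 0 and 0 in limma (127, 306 and 565 genes at an unadjusted p under 0.05).

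Genes that rose at least 2-fold after H93 lay next to each other more often than shuffled calls would. Among 11505 ordered genes 15 adjacent pairs were both called up, against a mean of 2.42 and a highest of 10 in 10000 shuffles (permutation p = 0.0001, the smallest they can give). For falls there were 2 pairs (permutation p = 0.18). The pairs included SERPINB5 and SERPINB7, SERPINB7 and SERPINB2, GKN2 and GKN1, KRT15 and KRT19, and HLA-DMB and HLA-DMA, which are tandem relatives, and also TNFAIP3 and PERP. That neighbouring genes rise together restates these 15 pairs and does not explain them, and how far tandem copies account for them was not tested.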
